A study of Mus musculus with 4 samples.

How the data were processed

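RNA was measured in 4 samples of mouse bone marrow cells on Illumina MouseRef-8 BeadChips, with 1 array for each combination of 2 genotypes (wild type, WT, and Btg1/Btg2 double knockout, dKO) and 2 sorted fractions (B220+CD43+ and B220+CD43- cells). Per the labels' protocols, marrow was flushed from tibia and femur, the fractions were sorted by flow cytometry, and biotin-labelled cRNA was made from total RNA purified on columns. Each array was assigned to its genotype and fraction from its title in the labels.

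The deposited signal table holds, per the file headers, a GenomeStudio 1.9.0 export with no normalization: a mean bead intensity per probe on the scanner's linear scale, the SD of the bead intensities, the number of beads and a detection score. The detection score is a fraction from 0 to 1, per the file headers, and it rose with the signal, so 1 minus the score was taken as the detection p. A second table holds the authors' RMA values on a log2 scale, with 1 value per gene. The authors also deposited in that table a linear ratio per gene, headed as WT against dKO, whose values equal dKO over WT. These ratios were not used. The series matrix holds the authors' log2 values for the same arrays, with column medians of 3.78 and 3.77 for WT and 3.79 and 3.77 for dKO (CD43+ first). Its values were identical to the RMA table wherever the identifiers matched, so its scale and direction are those of RMA. The RMA software settings are not given in the sources used here.

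The 25697 probes carried 18138 gene identifiers. Of these, 14308 matched a current symbol and 2894 a synonym in a RefSeq gene table (assembly GRCm38.p6), and 936 kept the name in the file. No coordinates are reported, because the array files name no genome build, and that table served for names and for the order of neighbouring genes. The result was 17916 genes, of which 5056 had several probes.

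Signals were background corrected, normalized and log2 transformed with neqc in limma 3.58.1 (R 4.3.3): normexp correction with the negative-control distribution inferred from the detection p, an offset of 16 and quantile normalization over the 4 arrays. The offset shrinks differences of dim genes. Each gene was represented by the probe with the highest mean over the 4 arrays. Values of a gene's other detected probes are given for some genes only, and several of them were smaller. A probe with a detection p under 0.01 was taken as detected, and a comparison covered the genes detected on at least 1 of its 2 arrays. Where a gene was detected on 1 of the 2 arrays, its difference is given as a bound ("at least N-fold"), taken against the higher of the gene's own value and the lowest detected value on the other array. Where it was detected on neither, no fold is given.

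A group held 1 array, so a difference between 2 groups has no test and genes were counted by size, with a threshold of 2-fold. An additive limma fit of genotype with fraction as a block (lmFit and eBayes, Benjamini-Hochberg adjustment, genes detected on at least 1 of the 4 arrays) was added after seeing the data. It leaves 1 residual degree of freedom, takes any genotype effect that differs between the fractions as noise, and treats the 2 fractions as independent although they may come from the same animals. The SE beside single genes is that of the beads on the 2 arrays, which covers the measurement on the chip and no difference between animals or RNA preparations. The number of arrays limits the precision. The 2 WT arrays and the 2 dKO arrays differed in mean signal (550.7 and 555.2 against 662.1 and 648.1), so genotype and array brightness cannot be told apart before normalization.

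Before the data were examined, 28 gene lists (cell cycle, B-lineage genes, signalling, stress, and markers of other marrow cells), 4 comparisons and the genes to be named were fixed. The named genes were Btg1, Btg2, Ebf1 and Pax5, the 8 genes with the largest difference in each direction whose sign was the same in the RMA table, up to 8 per direction that differed at least 2-fold in both fractions, and the 4 members of a described list with the largest differences. Predicted clones without a gene name were skipped. For each list with at least 3 tested members, the median log2 difference is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile describes these arrays and is not a p-value. Medians include genes detected on 1 array, and a median with such genes at their bound is given where it differs. The list of immunoglobulin genes had 1 member on the table and 0 detected members, so it was not analysed here. Single values of some list members are not reported here.

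The steps were tested on data simulated from the WT CD43+ array, for the comparison of dKO with WT CD43+ cells, with 2 models of noise. The first model gave every probe an independent background on every array (SD 10) and kept the signal of undetected probes. Of genes changed 3-fold, 50 of 50 higher and 47 of 50 lower genes came out at least 2-fold different, and of those changed 4-fold 50 and 49 of 50. Of 9596 unchanged genes, 309 (3.22%) also did, which is close to the 323 genes at least 2-fold different in the real comparison. The second model was built after this result had been seen. It split the background into an array-specific part (SD 7.81) and a probe-specific part (SD 4.32), estimated from undetected probes, and gave undetected probes no signal. It recovered 50 and 43 of 50 genes at 3-fold and 50 and 45 of 50 at 4-fold, and 11 of 8169 unchanged genes (0.13%) came out at least 2-fold different. The number of genes expected past the threshold by noise alone therefore depends on the model and is not settled between 11 and 309, and neither model includes differences between animals or RNA preparations. A list of 15 genes lowered 3-fold lay at percentile 0 with both models, and of 100 random lists 5 lay below percentile 5 with each.

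Alternatives fixed before the data were examined were the authors' RMA values and series matrix, no background correction, an offset of 50, scaling on the array median in place of quantiles, detection on both arrays, no detection filter, a detection p of 0.05, the mean of a gene's detected probes, and thresholds of 1.5-fold and 3-fold. Counting bounds in place of measured differences and the fit with fraction as a block were added after seeing the data. The sizes a difference must have for a change of sign to be counted as a reversal (1 for genes and 0.25 for list medians, on the log2 scale) were also set after the data were seen. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.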

Results

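Early B-lineage cells of mouse bone marrow were profiled in wild-type (WT) mice and in mice lacking Btg1 and Btg2 (dKO), which encode related antiproliferative proteins that bind the CCR4-NOT deadenylase complex. Cells carrying the B-lineage marker B220 were sorted by CD43 into a CD43+ fraction, which the labels equate with Hardy fractions A to C (pre-pro-B and pro-B cells), and a CD43- fraction, equated with Hardy fractions D to F (pre-B, immature and mature B cells). Each of the 4 groups was measured on 1 array, and no difference between 2 groups has a replicate check. The title of the series names B-lineage commitment and the activity of EBF1, the transcription factor that establishes the B-cell program, as its subject. The arrays detected 42.8% (WT CD43+), 40.2% (WT CD43-), 43.3% (dKO CD43+) and 39.5% (dKO CD43-) of 25697 probes, corresponding to 8159, 7647, 8253 and 7550 genes. A probe was read from a median of 38 to 39 beads, with a median bead SE of 4.00% to 4.06% of the signal. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were detected on all 4 arrays, and Uty in CD43+ cells only. Xist, expressed from the inactive X chromosome, was detected on all 4 arrays by 1 probe (signals of 208 and 181 in WT and 254 and 246 in dKO, CD43+ first) and in dKO only by its other probe (251 and 227, against 146 and 148 in WT). In the authors' RMA table Xist was higher in dKO by 1.79 and 1.99 on the log2 scale. The sexes of the animals are not known here.

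The targeted genes were examined first. Btg1 was measured by 2 probes. The brighter one gave signals of 8610 ± 276 (bead SE) in WT CD43+, 19425 ± 643 in WT CD43-, 3459 ± 102 in dKO CD43+ and 8115 ± 266 in dKO CD43- cells. Btg1 was thus 3.28-fold lower in dKO CD43+ cells (log2 difference -1.71, bead SE 0.066) and 2.72-fold lower in dKO CD43- cells (-1.44, bead SE 0.071), and the other probe gave -2.05 and -1.86. The position of the probes relative to the deleted part of the gene is not known here, so the remaining signal does not check the genotype. Btg2 was not detected on any of the 4 arrays (signals of 155.6, 142.3, 140.9 and 138.1, near the background mean of 140.38 to 145.78), and its loss could not be assessed. Ebf1 was 1.25-fold higher in dKO CD43+ cells (0.32, bead SE 0.153) and 1.18-fold higher in dKO CD43- cells (0.24, bead SE 0.154). Pax5, a B-cell identity factor downstream of EBF1, was not detected in either CD43+ sample and had a log2 difference of -0.31 (bead SE 0.195) between dKO and WT CD43- cells.

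**Figure D1:**
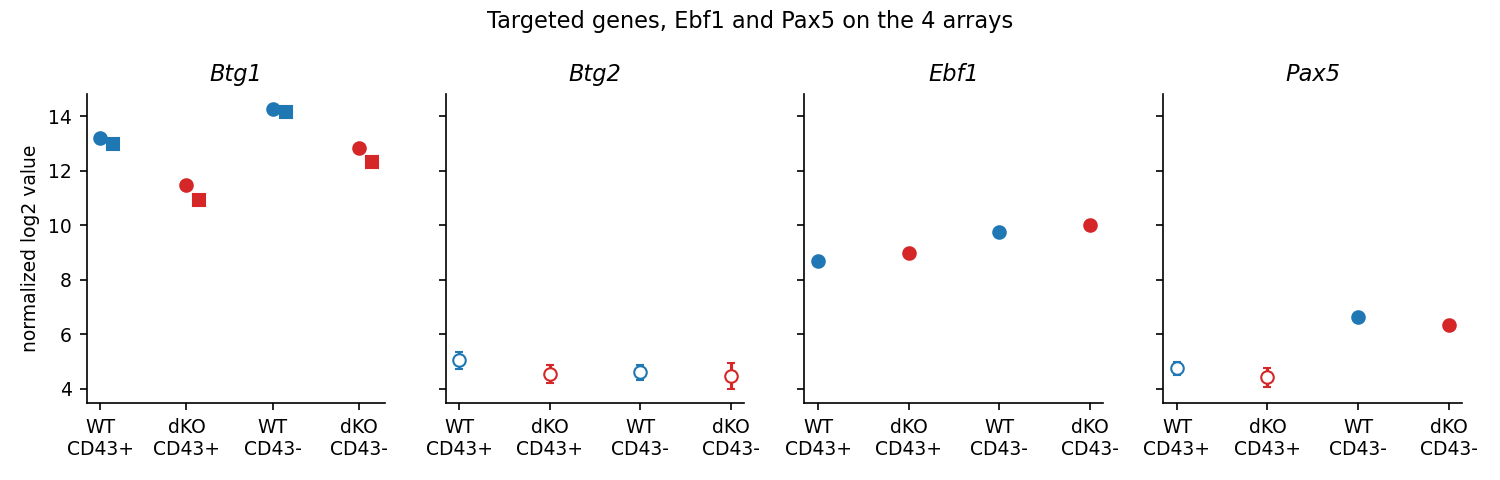
Normalized log2 values of Btg1, Btg2, Ebf1 and Pax5 on the 4 arrays (blue, WT; red, dKO; error bars, bead SE; open symbols, not detected; circles and squares, separate probes). Btg1 lies lower in dKO than in WT in both fractions by 1.44 to 2.05 log2 units over its 2 probes, and Btg2 is at background on all 4 arrays.

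The first comparison asked what the loss of BTG1 and BTG2 changed in CD43+ cells. Genes of neutrophil granules were lower in dKO CD43+ cells: Lcn2 was 7.39-fold lower (log2 -2.89, bead SE 0.117), Ngp 6.93-fold, Ltf, encoding lactoferrin, 6.15-fold and Chil3 6.0-fold. Haptoglobin (Hp, 6.18-fold), lysozyme (Lyz2, 5.89-fold) and Retnlg (5.75-fold) were lower too. Fcer1g, which encodes the signalling chain shared by several Fc receptors, was at least 211-fold lower, from a signal of 7546 in WT to one not above background in dKO. Ctse is among the 50 nearest tested genes on each side of Btg2, and Fcer1g, Fcgr3, Slamf6 and Cd48 are only among the 100 nearest. Whether the probes of these genes bind the dKO transcripts as well as the WT ones was not tested. Their folds therefore do not separate probe binding from RNA amount. In the other direction, Ctse, encoding cathepsin E, was 27.4-fold higher (4.78, bead SE 0.091), with signals of 10324 against 419, and Dctn1, a subunit of dynactin, was at least 9.65-fold higher.

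Further genes with large increases in dKO CD43+ cells were Gatad2b (at least 4.41-fold), Serpina3n (at least 3.64-fold), Gcnt2 (3.31-fold), Fcgr3, an Fc receptor for IgG (3.13-fold), Slamf6 (3.13-fold) and the histone gene H2bc4 (3.03-fold). The values of Gcnt2 and H2bc4 were 0.28 and 0.66 on the log2 scale in the authors' RMA table, against 1.73 and 1.60 here. H2bc4 belongs to a family of near-identical genes whose transcripts one probe may not separate. In all, 150 of 8631 tested genes were at least 2-fold higher and 173 at least 2-fold lower, and 5 and 24 were at least 4-fold so. Counting genes detected on 1 array by their bound left 101 and 124. Noise alone put 11 or 309 simulated unchanged genes past this threshold, depending on the noise model, so the counts by themselves are weak evidence of a genotype effect. The split was 89 higher and 316 lower when arrays were scaled on their median, a scaling that moved the median of all genes by -0.051, and 11 and 38 without background correction and 39 and 77 with an offset of 50. Of the 56 genes with a second detected probe, 50 had the same direction on it.

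Among the fixed lists, 15 of 15 tested neutrophil and granulocyte progenitor markers were below 0 in dKO CD43+ cells, 10 of them at least 2-fold lower, with a median of -1.94 (-1.34 with bounds) that lay below all 10000 random lists (percentile 0.0). Without background correction that median was -0.61. Of the primary-granule genes, which are expressed at the promyelocyte stage, ELA2 was past the 2-fold threshold (-1.16), and Mpo (-0.79), Ctsg (-0.68) and Prtn3 (-0.31) were not. Monocyte and macrophage markers went both ways (median -0.06), from Lyz2 (-2.56) and Lyz1 (-2.16) to Ms4a6c (0.88 or more) and Fcgr3 (1.65). NK-cell markers were above 0 in 11 of 11 cases and at least 2-fold higher in 1 (median 0.65, percentile 99.99), with Eomes at 1.10, Tbx21 at 0.85, Il2rb at 0.84 and Klrk1 at 0.72. T-cell markers had a median of 0.19 (percentile 81.7) and plasmacytoid dendritic cell markers one of 0.15 (percentile 82.01).

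Of the genes of the B-lineage program in CD43+ cells, the transcription factors had a median of 0.26 (percentile 99.64), with 14 of 18 above 0. These samples also held markers of other cells, and NK-cell markers had a median of 0.65 in the same comparison. Whether the shift lies in B-lineage cells or in other cells of the fraction was not tested. Runx1 was at 1.19, Myb at 0.75 (-0.23 on its other detected probe) and Bach2 at 0.71, whereas Tcf3, encoding the E proteins E12 and E47, was detected in WT only and lay at -0.76 or below. None of 10 EBF1 target genes differed by 2-fold (median -0.08, percentile 12.52); Blnk was at -0.51, Vpreb3 at -0.33 and Cd55 at 0.33. Pro-B and early progenitor genes had a median of 0.21 (percentile 93.04), including Rag1 at 0.66, Lef1 at 0.70 and Bst1 at 0.61. Immediate-early genes had a median of -0.39 (-0.35 with bounds, percentile 0.0), with 11 of 15 below 0 and 1 at least 2-fold lower, and with Fosb at -1.15, Junb at -0.68, Fos at -0.68 and Egr2, against the trend, at 0.87. Heat-shock and stress genes had a median of -0.48 (percentile 0.01), with 7 of 11 below 0 and 4 above. Hspa8, at -1.08, was the only member at least 2-fold lower, and Hspa5 went the other way, at 0.70. The lists of S phase (0.11, percentile 85.87) and G2/M genes (-0.15, percentile 5.08) held no member at 2-fold.

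The second comparison asked the same of the more mature CD43- cells. Here 6 of 8 tested markers of plasmacytoid dendritic cells were at least 2-fold higher in dKO, and genes of DNA replication and mitosis had medians above 0 with most members within 2-fold. Siglech, a plasmacytoid dendritic cell receptor, was 7.72-fold higher (2.95, bead SE 0.153, but 1.76 on its other detected probe), P2ry14 6.0-fold, the tissue kallikrein Klk1 5.35-fold and the cyclin Ccnd1 5.32-fold. The histone H4 genes H4c3 and H4c12 were 5.47-fold and 5.04-fold higher, Ctse was 21.0-fold higher and Dctn1 at least 8.67-fold higher. The lowest genes were Cd48, a SLAM-family ligand (at least 4.82-fold lower), Fcer1g (at least 4.09-fold), Pde1b (3.98-fold), Mthfsd (at least 3.80-fold), Dennd6b (3.62-fold), the translation factor gene Eif4b (3.54-fold), Ppcdc (3.53-fold) and Erdr1 (3.40-fold).

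In total, 290 of 7944 tested genes were at least 2-fold higher in dKO CD43- cells and 206 at least 2-fold lower, with 25 and 4 at 4-fold or more. With genes detected on 1 array at their bound, 187 and 99 remained past the threshold. With median scaling the counts were 235 and 232, so the excess of higher genes depends on the scaling, and they were 50 and 34 without background correction and 116 and 60 with an offset of 50. A second detected probe existed for 68 of these genes and had the same direction for 63. The H4 genes encode identical proteins and Klk1 has close paralogs, so their probes may read several genes.

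Plasmacytoid dendritic cell markers were above 0 for 8 of 8 tested genes in dKO CD43- cells, 6 of them at least 2-fold (median 1.35, above all random lists, percentile 100): beside Siglech and Klk1 these included Cox6a2 (1.51) and Pacsin1 (1.44), although Pacsin1 was at -0.02 in the authors' RMA table. Of S-phase genes, 20 of 22 were above 0 and 3 at least 2-fold higher, with a median of 0.66 (percentile 100), including Cdc6 at 1.14, Mcm2 at 1.12, Ccne2 at 1.01 and Uhrf1 at 0.98. Of G2/M genes, 14 of 15 were above 0 and 1 at least 2-fold higher, with a median of 0.54 (percentile 99.99), among them Ccna2 at 1.32 or more (detected in dKO only), Ccnb1 at 0.80 and Cdc20 at 0.69 (-0.36, 0.35 and 0.39 on its other detected probes), and Tacc3 at -0.33. T-cell markers had a median of 0.63 over 5 tested genes (0.43 with bounds), with Cd8b1 at 2.28 and Lck at 0.63, and NK-cell markers one of -0.09 over 5 genes, with Klrd1 at 1.92 and Nkg7 at -0.59. Interferon-stimulated genes had a median of 0.40 (percentile 99.79; 0.13 in the authors' RMA table), with Ifit2 at 1.15 and Irf7 at 0.89; Irf7 and Bst2 of that list are also plasmacytoid markers.

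Most B-lineage genes stayed within 2-fold between dKO and WT CD43- cells. Mature B-cell genes had a median of -0.17 (percentile 1.5) with 0 of 19 at 2-fold, among them Tnfrsf13c at -0.55, Cd37 at -0.52 and Ciita at 0.56. EBF1 target genes had a median of -0.05 (percentile 28.58), with 1 of 11 members at least 2-fold lower, Blnk at -0.32 and Vpreb1 at 0.91. Lineage transcription factors had a median of 0.13 (percentile 91.68), with Runx1 at 1.0 and Ets1 at 0.51, and pro-B genes one of 0.17 (percentile 92.07). Genes of V(D)J recombination and end joining had a median of -0.25 (percentile 3.24; -0.16 in the authors' RMA table), with 5 of 11 above 0: Polm, a polymerase of the end-joining pathway, was at -1.47, Dclre1c, encoding Artemis, at -1.0 (-0.83 and 0.16 on its other detected probes), Nhej1 at -0.76, Lig4, encoding DNA ligase IV, at 0.57 and Dntt at 0.48. Immediate-early genes had a median of -0.56 (percentile 0.0), with 10 of 14 below 0 and 2 at least 2-fold lower: Fosb was at -1.50, Fos at -1.26, Junb at -0.83 and Dusp1 at -0.71. Genes of IL-7 receptor signalling and survival had a median of 0.29 (percentile 99.4; 0.09 in the authors' RMA table), with Socs3 at 1.08, Socs2 at 0.88, Cish at -0.64 and Jak1 at 0.49.

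**Figure D2:**
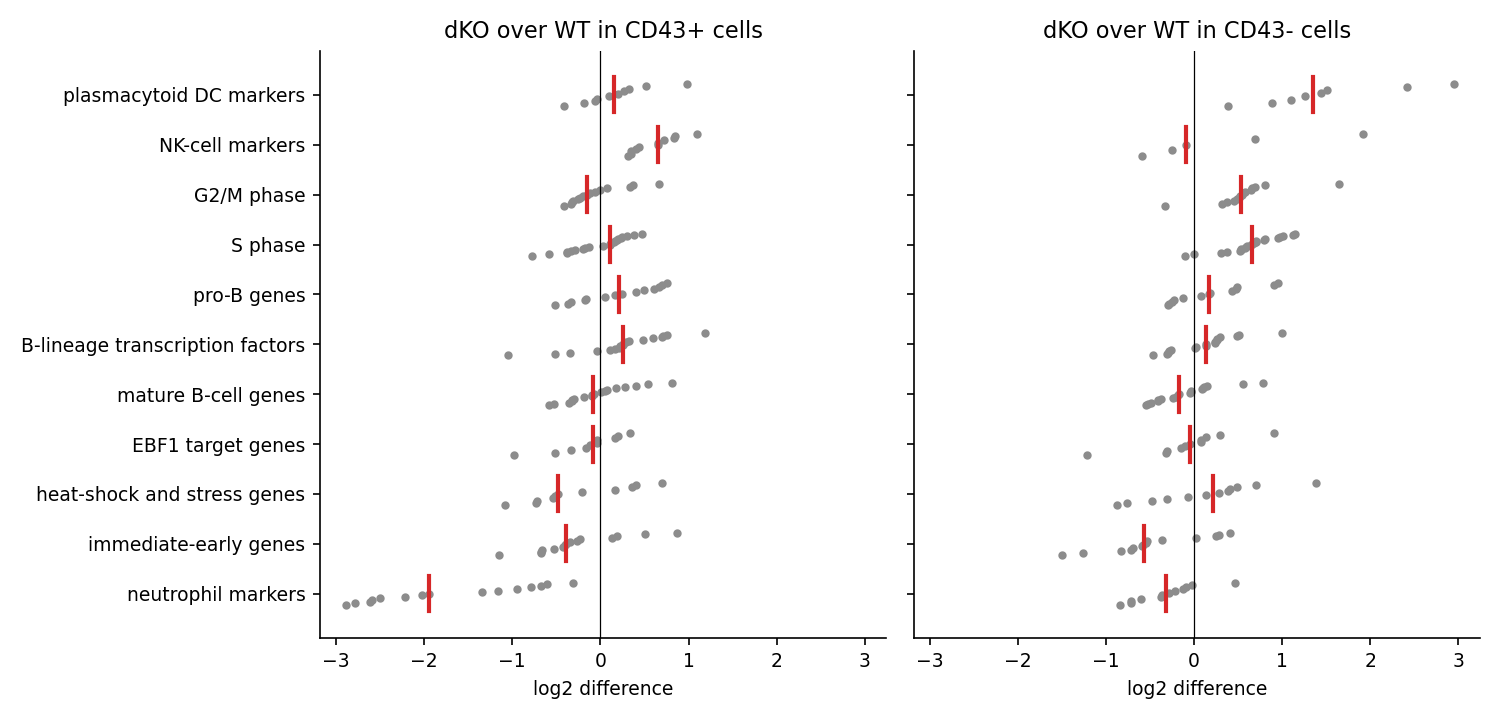
Log2 difference, dKO over WT, of each tested member (grey points) of 11 fixed gene lists in CD43+ cells (left) and CD43- cells (right), with the list median as a red line. Neutrophil markers have a median of -1.94 in CD43+ cells, and plasmacytoid dendritic cell, S-phase and G2/M genes have medians of 1.35, 0.66 and 0.54 in CD43- cells.

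The genotype differences of the 2 fractions, which share no array, were set against each other. Ctse, Dctn1, Fcgr3, Lmnb1, Gatad2b, H4c3, Sec24d and Slamf6 were higher in dKO in both fractions, and Cd48, Fcer1g, Eif4b, Pde1b, Erdr1, Zfp692, Lgals4 and Btg1 were lower in both. Lmnb1, which encodes the nuclear lamina protein lamin B1, was 2.86-fold and 3.91-fold higher (CD43+ first; its other detected probe gave 0.49 and 1.63 on the log2 scale). Sec24d was 2.47-fold and 2.83-fold higher. Zfp692 was 5.28-fold and 3.34-fold lower (-1.58 and -1.85 on the log2 scale on its other detected probe) and Lgals4, encoding galectin-4, 3.15-fold and 3.27-fold lower. Over 7613 genes tested in both fractions, 38 were at least 2-fold higher in both, against 2.9 for independent lists, 51 were lower in both, against 2.3, and 2 had opposite directions. The counts were 3 and 12 without background correction and 12 and 24 with an offset of 50. An additive limma fit over the 4 arrays, with fraction as a block and 1 residual degree of freedom, was added after seeing the data. It put 2 of 8962 genes past a Benjamini-Hochberg adjusted p of 0.05: Ctse (log2 4.58, adjusted p = 0.0199, higher in 2 of 2 fractions) and Dctn1, and 0 genes lower (Btg1 -1.58, adjusted p = 0.172, lower in 2 of 2 fractions). Dctn1 was not detected on the WT arrays, so its place in this fit rests on WT values not above background, and the supported differences are the bounds of 9.65-fold and 8.67-fold. The correlation across genes was r = 0.522 (Spearman's rho 0.503; r = 0.326 without a detection filter), where genes are not independent replicates and where both fractions of a genotype may come from the same animals.

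**Figure D3:**
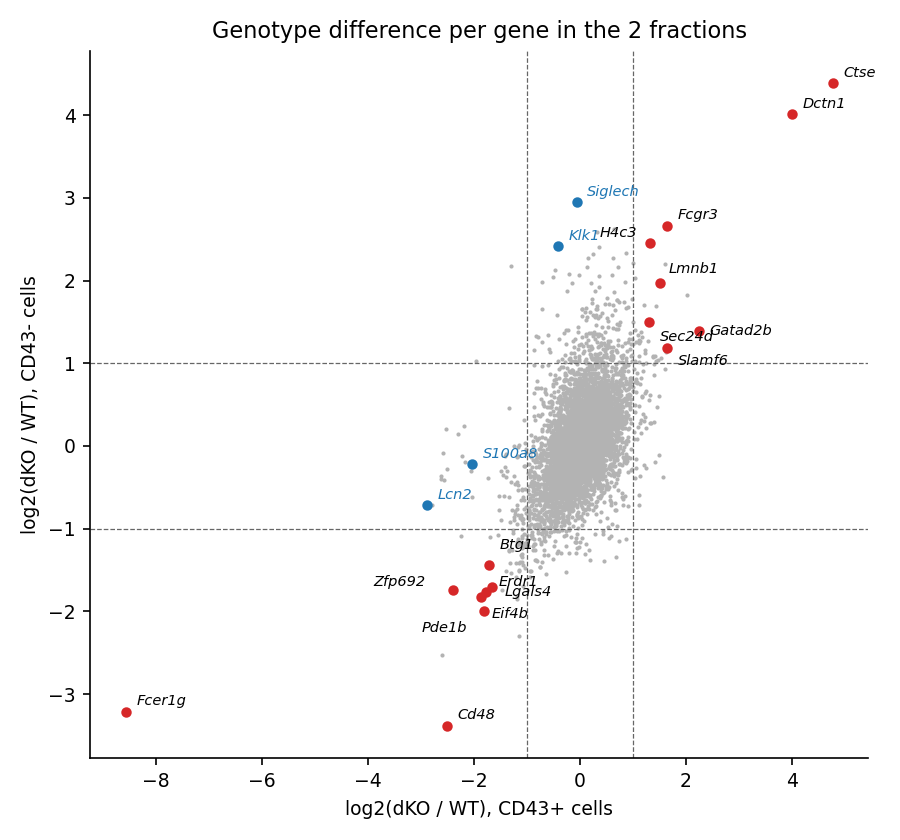
Log2 difference between dKO and WT in CD43+ cells (x) and CD43- cells (y) for 7613 genes (grey), with dashed lines at 2-fold. Red points are the named genes that differ at least 2-fold in both fractions, such as Ctse at 4.78 and 4.39; blue points are Siglech, Klk1, Lcn2 and S100a8, which differ at least 2-fold in 1 fraction.

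The last 2 comparisons set CD43- against CD43+ cells within each genotype. These fractions differ in B-cell stage and also in their content of other cells, as markers of plasmacytoid dendritic, NK and T cells were among the largest differences. In WT, genes of mature B cells were higher in CD43- cells: the IgE receptor gene Fcer2a was 37.7-fold higher (5.23, bead SE 0.214), Cd40 16.7-fold and the complement regulator gene Cd55 14.4-fold, along with Reln (23.5-fold), Prm1 (19.5-fold), Klhl14 (17.7-fold), the cannabinoid receptor gene Cnr2 (17.7-fold) and Prg3 (14.2-fold). The lowest genes in WT CD43- cells included the plasmacytoid dendritic cell markers Siglech and Klk1: Siglech was 110-fold lower and Klk1 57.5-fold, beside Ccnd1 (94.9-fold), P2ry14 (85.2-fold), Klra17 (67.8-fold), Atp2a1 (at least 64.7-fold), Klk1b27 (61.1-fold) and Klk1b4 (58.7-fold). Klra and Klk1 genes are families of close paralogs. Btg1 was 2.09-fold, Ebf1 2.12-fold and Pax5 at least 2.45-fold higher in CD43- than in CD43+ WT cells.

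In dKO, the same direction held for Fcer2a (at least 40.8-fold higher in CD43- cells), Klhl14 (at least 18.5-fold), Prg3 (18.3-fold), Reln (17.7-fold), Gh (at least 17.2-fold), Cd40 (14.9-fold), the chemokine receptor gene Ccr6 (13.9-fold) and Ms4a1, encoding CD20 (at least 13.7-fold). The other detected probes of Fcer2a gave smaller log2 differences of 2.94 and 3.24. The lowest genes in dKO CD43- cells included the NK-cell markers Ccl5 (72.9-fold lower), Nkg7 (67.5-fold) and Klra7 (38.5-fold) and the T-cell marker Thy1 (44.4-fold), beside Klra4 (at least 51.0-fold), Ccl4 (42.9-fold), Ctsw (38.9-fold) and Klre1 (at least 36.4-fold). Btg1 was 2.52-fold, Ebf1 2.02-fold and Pax5 at least 2.02-fold higher in CD43- cells. The WT comparison counted 670 of 8539 genes at least 2-fold higher and 954 lower, and the dKO comparison 515 of 8495 higher and 901 lower (534 and 730, and 458 and 683, with bounds). Of 8072 genes tested in both, 349 were higher in both (34.7 for independent lists), 683 lower in both (94.3) and 1 opposite, with r = 0.888 across genes (rho 0.793).

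Mature B-cell genes had medians of 2.53 in WT and 2.07 in dKO (2.47 and 1.97 with bounds), with 15 of 19 at least 2-fold higher in each, and EBF1 target genes medians of 1.52 and 1.42 (1.33 and 1.30 with bounds), where Vpreb1, a surrogate light chain gene of pro-B cells, went the other way (-2.70 and -1.63). Dntt, encoding the terminal transferase of pro-B cells, was at -4.20 and -3.54. Plasmacytoid markers had medians of -3.92 and -3.10 (-3.62 and -3.06 with bounds), NK-cell markers -3.51 and -3.68 (-2.32 and -2.97 with bounds) and T-cell markers -2.73 and -2.66 (-2.12 and -1.87), each at percentile 0.0. S-phase genes had a median of -0.53 in WT (percentile 0.02; -0.35 in the authors' RMA table) and 0.08 in dKO (percentile 58.6), and G2/M genes -0.32 (percentile 1.78) and 0.34 (percentile 97.5); whether these differ between the genotypes could not be tested. Quiescence genes had medians of 1.01 and 0.80 (6 of 12 and 4 of 11 at least 2-fold higher in CD43- cells), with Klf2 at 1.75 and 1.45 and Cdkn1b at 1.24 or more and 1.32. Erythroid markers had medians of 1.04 and 1.34 (5 of 9 and 6 of 10 at least 2-fold higher), with Alas2 at 1.64 and 1.92. Neutrophil markers were lower in CD43- than CD43+ cells in WT (-1.35, -1.07 with bounds, percentile 0.0) and at 0.19 in dKO (percentile 72.53).

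**Figure D4:**
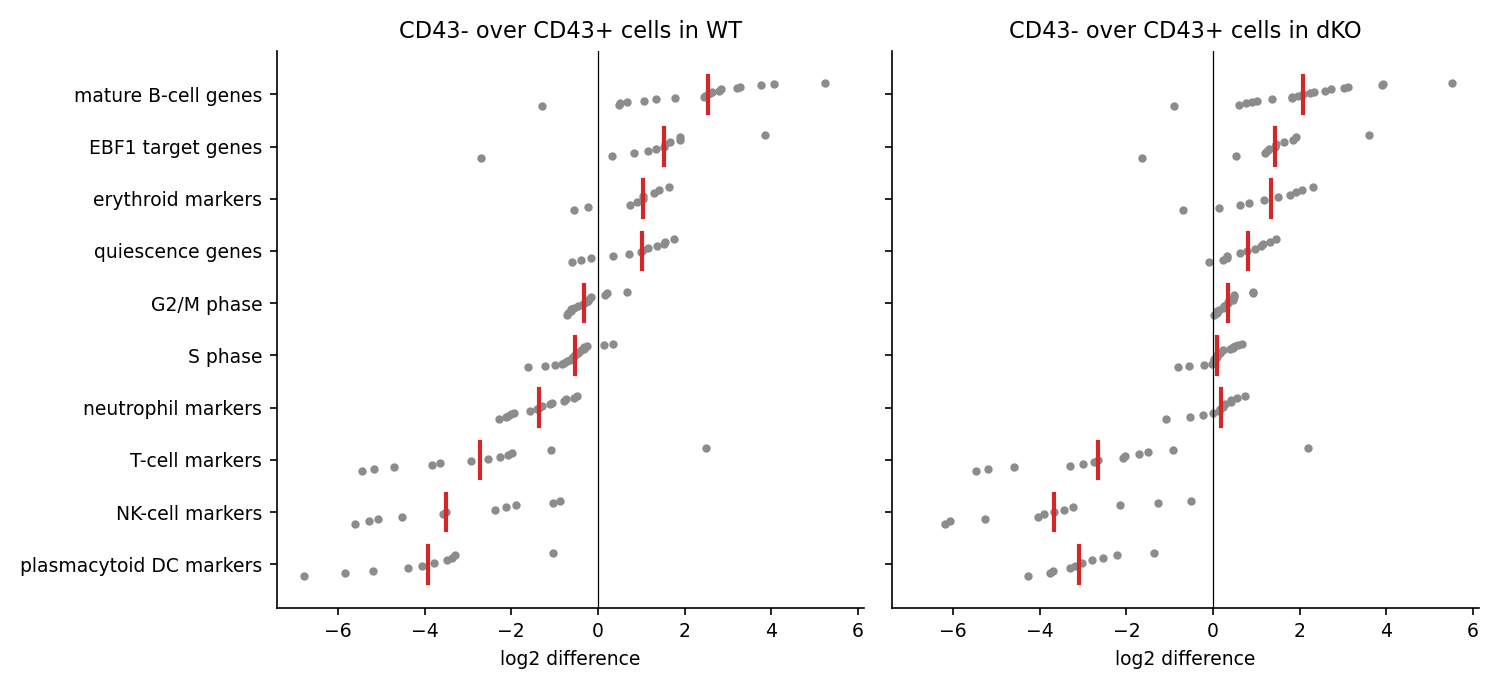
Log2 difference, CD43- over CD43+ cells, of each tested member (grey points) of 10 fixed lists in WT (left) and dKO (right), with the median as a red line. Mature B-cell genes have medians of 2.53 and 2.07 and plasmacytoid dendritic cell markers of -3.92 and -3.10.

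The remaining lists showed smaller differences between dKO and WT, given here for CD43+ and then CD43- cells. Members of the BTG/TOB family and the CCR4-NOT complex had medians of 0.04 and -0.07, and Btg1 was their only member at 2-fold. Arginine methyltransferases, the family of the BTG1 partner PRMT1, were at -0.24 (percentile 4.74, 0 of 7 above 0) and -0.14 (percentile 16.13), the latter at 0.01 in the authors' RMA table. Medians were -0.05 and -0.09 for pre-BCR and BCR signalling, 0.01 and 0.08 for p53 targets (-0.04 in CD43+ cells with median scaling), 0.23 and 0.05 for quiescence genes, 0.05 and 0.50 for stem and progenitor markers (-0.04 in CD43+ cells with median scaling; 0.30 in CD43- cells with bounds and 0.32 in the authors' RMA table), -0.04 and 0.11 for plasma-cell markers, -0.21 and -0.04 for erythroid markers, and -0.08 and 0.18 for basophil, mast-cell and eosinophil markers. In CD43+ cells the median was -0.16 for V(D)J recombination, 0.08 for IL-7 receptor signalling, 0.22 for interferon-stimulated genes, -0.08 for mature B-cell genes and 0.41 (0.28 with bounds) for 3 stromal and endothelial markers. In CD43- cells it was 0.21 for heat-shock genes, -0.32 (-0.25 with bounds) for neutrophil markers and -0.07 for monocyte markers. In the authors' RMA table some small medians had the other sign: IL-7 receptor signalling (-0.11), mature B-cell genes (0.02) and BCR signalling (0.04) in CD43+ cells, and heat-shock genes (-0.03), p53 targets (-0.12) and quiescence genes (-0.02) in CD43- cells. The list of sex-linked genes had medians of 0.12 and -0.09, over Xist and Y-linked genes that mark opposite sexes, with Eif2s3y at -0.88 in CD43- cells.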

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

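All tests of explanations in this part were chosen after the patterns had been seen, and the rules of the Btg1, Btg2, granulocyte RNA and plasmacytoid tests were revised after earlier versions had given values. The list medians below had opposite signs in dKO CD43+ and dKO CD43- cells, with 1 array per group, and the difference between fractions was not tested. Each value is the median, over members tested in both fractions, of CD43- minus CD43+. It can be near 0 or of the other sign than the step between the medians, whose members differ. It was 0.70 for genes of G2/M, -0.738 for NK-cell markers, 0.47 for basophil, mast-cell and eosinophil markers, 0.061 for BTG/TOB and CCR4-NOT genes (medians of 0.04 and -0.07), 0.05 for heat-shock and stress genes (medians of -0.48 and 0.21) and 0.031 for plasma-cell markers, so the median member of the last 3 lists hardly differed between fractions. Of single genes, Cd209d was at -1.30 in CD43+ and 2.17 in CD43- cells (at least 1.86, as WT was not detected), a difference of 3.471, of which the bound supports 3.16. Fcgr4 was at -1.97 and 1.03, a difference of 2.997, but the bound of 0.33 in CD43- cells supports 2.29 and does not reach 2-fold there. Both were picked after their values were seen.

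Genes at least 2-fold different in dKO in both fractions were placed by gene order (GRCm38.p6), since strain DNA can be carried along with a targeted locus. The 100 nearest genes on each side of Btg2 held 8 of them (Gm7609, Ctse, Ivns1abp, Uap1, Fcgr3, Fcer1g, Cd48 and Slamf6), against at most 7 in 10000 random windows on other chromosomes. The 50 nearest on each side held 2 (percentile 75.12), and all 3 widths were tried. The 200 nearest held 12 (percentile 100), but that window spans 368 of the 377 tested genes of chromosome 1, so it says nothing of position. The shares were 2.0% at 50, 4.0% at 100 and 3.2% over chromosome 1. An excess around Btg2 is thus not separated from one along the chromosome. Around Btg1 there was 1 (Mdm1) at each width, against random medians of 1 to 2 and 95th percentiles of 3 to 6. That is no excess, but strain DNA that changes few genes 2-fold would give a like count. Strain DNA carried along with the Btg1 locus therefore stays open. Strain DNA carried along with Btg2 may contribute to the differences in Ctse, Fcer1g and Cd48, but the windows do not settle this. Whether it would act through RNA amount or through probe binding was not tested. It leaves open the 73 of 83 placed genes outside both windows. Brightness of the dKO arrays cannot be told apart from genotype, although 89.9% of these genes stayed at least 2-fold different the same way after median scaling, and an effect of BTG1 and BTG2 loss stays open as well.

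Neutrophil markers were lower in dKO CD43+ cells, where 66.7% of the 15 tested ones were at least 2-fold lower. Granulocyte RNA in the WT CD43+ library may account for this and stays open. A B220+ gate is meant to remove such cells, yet S100a8 and S100a9 gave signals of 1928 or more on all 4 arrays. The markers short of 2-fold had WT CD43+ signals of 176 to 361. Cebpe, Mmp9 and ELA2 passed 2-fold with like signals of 214 to 232, and Mpo, at 361, did not. Low signal alone therefore does not account for the split. The share of 66.7% lay between the limits set for either answer and decides neither way. An earlier version that used only members bright in WT favoured this explanation and was dropped. The most abundant genes, S100a8 and S100a9, went from 12958 and 6498 in WT to 4272 and 1928 in dKO, near their levels in WT CD43- cells (4863 and 2299). With median scaling the list median was -2.08, so the difference does not rest on the choice of quantiles over the array median. That scaling moved the median of all genes by -0.051, so it could do little to a list this far from 0. It therefore does not decide on array scaling in general. Without background correction the list median was -0.61. Lower granulocyte gene expression within B-lineage cells of the dKO stays open, as the median of -0.32 in CD43- cells does not decide it.

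Plasmacytoid dendritic cell markers were higher in dKO CD43- cells, where 6 bright ones (signal over 2000 on both CD43+ arrays) held a median of 11.4% of their CD43+ value against 4.76% in WT. More plasmacytoid dendritic cells in the CD43- gate may account for this, as a B220+ gate keeps them. All 6 gained share, by a median of 6.78 percentage points, from 1.40 for Bst2 to 10.6 for Klk1. The rule asked for an even gain, within 3 times the median either way. Bst2 alone, which is also on the interferon-stimulated list, missed it, so by that rule the test did not decide. Siglech signals were 1176 in dKO and 228 in WT CD43- cells. Carry-over of all CD43+ cells is not decided either. Of 6 bright NK and T markers (median share 3.87% in dKO and 2.19% in WT), 3 had a lower share in dKO (Nkg7 1.09% from 2.44%, Ccl5 1.21% from 2.30%, Thy1 1.83% from 2.09%). All 3 lay below the lowest plasmacytoid share in dKO (7.20%, Siglech). For these 3 markers that argues against an equal carry-over of all CD43+ cells. Their fall from WT is weak evidence, as their dKO CD43- signals (190 to 267) were near background. Their CD43+ signals were also higher in dKO. The other 3 had a higher share (Klrd1 5.91% from 1.80%, Cd8b1 9.65% from 1.79%, Lck 34.8% from 24.9%). A first version of that test used 3 NK markers only (median 1.21%) and would have excluded carry-over. The first version of the other asked only for a gain in all 6 markers, and would have been met.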

How the results depend on the processing

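The alternatives were planned except the count by bounds and the fit with fraction as a block, which were chosen after seeing the data, as were the sizes from which a change of sign was counted. No paired analysis was possible because each comparison of 2 groups held 1 pair of arrays, apart from a fit of genotype over all 4 arrays with fraction as a block, in which limma put 2 genes higher and 0 lower in dKO past an adjusted p of 0.05. Leaving out replicates was not possible for the same reason. The cause of the changes below was not tested, except that a threshold or a filter changes how many genes can pass. Using the mean of probes or a detection p of 0.05 kept every count within 1.5 times. Counts are given as higher and then lower.

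With a 1.5-fold threshold the counts were 788 and 665 for dKO over WT in CD43+ cells, 821 and 703 in CD43- cells, 1651 and 1682 for CD43- over CD43+ cells in WT, 1299 and 1512 in dKO, and 208 and 238 for genes different in dKO in both fractions. With a 3-fold threshold they were 14 and 37, 63 and 13, 211 and 517, 177 and 455, and 5 and 8, in the same order. Without background correction they were 11 and 38, 50 and 34, 247 and 425, 207 and 389, and 3 and 12. With an offset of 50 the genotype counts were 39 and 77 in CD43+ and 116 and 60 in CD43- cells, genes higher in CD43- cells numbered 388 in WT and 335 in dKO, and 12 and 24 differed in both fractions.

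With detection on both arrays the genotype counts were 82 and 106 in CD43+ and 160 and 90 in CD43- cells, genes lower in CD43- cells numbered 520 in WT and 499 in dKO, and 24 were higher in dKO in both fractions. The authors' RMA table gave 381 and 354 in CD43+ cells, 328 lower in CD43- cells and 88 lower in both. Their series matrix gave 380 and 353 in CD43+ cells, 328 lower in CD43- cells and 88 lower in both. Median scaling gave 89 and 316 in CD43+ cells, and bounds gave 187 and 99 in CD43- cells. The correlation across genes between the genotype differences was 0.326 without a detection filter.

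Of 454 single-gene differences recomputed, Bbc3 (CD43- over CD43+ in WT) turned to 0.305 and Pacsin1 (dKO over WT in CD43- cells) to -0.017 in both the RMA table and the series matrix. Of 103 list medians, that of stromal and endothelial markers between dKO fractions turned to -0.172 in the RMA table and the series matrix and to -0.019 without a detection filter. With detection on both arrays, stem and progenitor markers between WT fractions turned to -0.695 and plasma-cell markers between dKO fractions to 0.059. Without background correction list medians for dKO over WT shrank: neutrophil and granulocyte progenitor markers in CD43+ cells to -0.614, NK-cell markers in CD43+ cells to 0.416, heat-shock and stress genes in CD43+ cells to -0.203, immediate-early genes in CD43+ cells to -0.178, plasmacytoid dendritic cell markers in CD43- cells to 0.885 and T-cell markers in CD43- cells to 0.278. Medians for CD43- over CD43+ cells shrank too (WT, then dKO): NK-cell markers to -1.468 and -1.797, T-cell markers to -1.487 and -1.302, and quiescence genes to 0.595 and 0.50. Neutrophil markers in WT came to -0.439. Signal over background limits the dim genes: 850 and 691 genes of the CD43+ and CD43- genotype comparisons were detected on 1 array and have a bound in place of a fold.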

Other observations

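Myeloid genes of the bone marrow did not move as a block between the fractions. The complement genes C1qb and C1qc, typical of tissue macrophages, were higher in CD43- than CD43+ cells (C1qb at least 1.95 in WT and 1.37 in dKO, C1qc at least 1.19 and at least 1.27), as was the adhesion molecule gene Vcam1 (at least 2.0 and 1.75). Lyz2 (-3.15 and -1.01) and F13a1 (-2.76 or below and -1.54) were lower. Of interferon-stimulated genes, 11 of 14 in WT and 9 of 12 in dKO were below 0 (medians of -0.57, or -0.12 with bounds, and -0.70). Bst2 (-3.37 and -3.18), Irf7 (-3.30 and -2.22), Usp18 (-2.23 and -1.99) and Oasl2 (-1.65 and -1.12) were lower in CD43- cells, and Oas2 (at least 0.80 and at least 0.67) was higher.

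Of genes of IL-7 receptor signalling and survival, whose medians between fractions were -0.04 in WT and 0.05 in dKO, some members differed by fraction and others did not. Bcl2l1, encoding BCL-XL, was higher in CD43- cells (1.97 in WT and 2.35 in dKO), Bcl2 was at -0.15 and -1.23 (-0.40 in dKO on its other detected probe), and Il7r was at 0.06 and 0.00. Of the feedback regulator genes, Cish (-1.09 and -1.63) and Socs2 (-1.60 and -0.45) were below 0 in both genotypes, and Socs1 was above 0 (at least 0.77 and at least 0.64). The polymerase gene Polm was higher in CD43- cells (3.61 and at least 2.78), and Lig4 was at 1.24 and 1.69.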
